A study of Mus musculus with 6 samples.

How the data were processed

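RNA was measured in 6 libraries of CD11c-sorted cells from mouse tumours harvested on day 28, 3 from tumours of Gli2CA cells and 3 from tumours of control cells. Per the labels' protocols, tumours were digested with collagenase and DNase, CD11c-positive cells were sorted by flow cytometry, and RNA was isolated with a column kit. Messenger RNA was purified on poly-T beads and libraries were made with the NEBNext Ultra II kit, with random hexamer priming. The authors deposited 1 table of FPKM values with 54532 Ensembl gene IDs and 1 column per library, as its name and values show. The aligner, counting tool, genome build and annotation behind those values are not given in the sources used here. It is also not given whether the counting used strand, so overlapping and antisense genes cannot be told apart. Columns were matched to samples by the number in the sample descriptions. Libraries are named here by the number in the sample titles, so NTC 3 is the library whose description has the number 4.

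Gene symbols came from a table of gene IDs, which named 54409 of the IDs, and gene types, coordinates and lengths from GENCODE M21 on GRCm38, which held 54495 of them. Coordinates are those of that annotation, counted from 1. Each FPKM value times the mean transcript length of its gene was a whole multiple of 1 step per library. Among low values, 96.6 to 97.9% were whole within 0.05 of a read, depending on the library. The steps gave about 18790000 to 29130000 fragments per library. At the median gene length 1 read was worth 0.0218 FPKM in the deepest library and 0.0338 in the shallowest, and such floors cover counting error only. Numbers of detected genes were compared after thinning the recovered reads to 18780000 per library.

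The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with group as the only term, moderated variances with a trend on mean expression, and two-sided p-values with Benjamini-Hochberg adjustment over the 12266 genes with a mean of at least 1 FPKM. The threshold was an adjusted p of 0.05. FPKM are not counts, so no count model was the main test. Of the genes tested, 10817 were protein-coding. Before the data were examined, 35 gene lists with 548 entries were fixed, for cell types a CD11c gate could hold and for pathways related to the study's subject. A symbol with more than 1 ID was represented by the ID with the higher mean. The 31 lists with at least 5 tested members were tested with limma's camera, a competitive test, with a preset correlation of 0.01 and adjustment over the 31 lists. Camera with an estimated correlation and fry, which tests whether the members move on balance one way, were alternatives. Counts of members adjusted over the list alone used the same p-values. Gene groups named by symbol in the closing part, with pseudogenes left out, were chosen after the data were seen. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

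Named genes were fixed by a rule before the data were examined. It took the 10 protein-coding genes with the largest change in each direction that passed, or those with the smallest p where none did, up to 4 members of each list with the smallest p, and a fixed set of genes of the pathways and subsets under study. Genes named outside that rule are said to be so or are given as counts.

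The test was run on simulated data with the real means and number of samples, with 200 of 12266 genes changed. At the real spread of the Gli2CA and NTC comparison, 0%, 10%, 30% and 42% of genes changed by a log2 of 1, 2, 3 and 5 were recovered, with 0 false calls. A log2 change of 1 in the 21 interferon genes alone was called, as the 1 list among 31, and 0 lists were called with no change. The simulated noise was independent between genes. It therefore does not show how often lists are called falsely when their members vary together. With 3 libraries against 3, an exact permutation test of a single value cannot give a p below 0.1.

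Alternatives were a pseudocount of 0.1, no filter, a minimum mean of 5, rescaling to one sum per library, median-of-ratios scaling, quantile normalization, variances without trend or made robust, library weights, protein-coding genes alone, the replicate numbers as a block, and leaving out each library. Added after seeing the data were limma's voom on the recovered reads, a minimum mean of 20, and leaving out both NTC 1 and NTC 3. The last leaves 1 NTC library, which is assumed to vary like the Gli2CA group. No column or sample was left out of the main comparison.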

Results

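RNA was sequenced from cells sorted out of mouse melanomas on the surface integrin CD11c, which the labels call dendritic cells, the antigen-presenting cells that prime T cells. The tumours grew from a BRAFV600E melanoma line implanted into C57BL/6 mice and were harvested on day 28. In 1 group the implanted cells carried an active form of the Hedgehog pathway transcription factor Gli2 (Gli2CA, 3 libraries). In the other they carried a non-targeting control (NTC, 3 libraries). The genetic difference was therefore in the tumour cells, and the libraries measured the CD11c-sorted cells around them. The series title names immune evasion, Wnt ligands and prostaglandin signalling as its subject. The comparison asks how the CD11c-sorted cells differed between the groups. The deposited values were FPKM, fragments scaled to transcript length and library size. Fragment numbers recovered from them came to about 18790000, 27880000 and 23170000 for NTC 1, NTC 2 and NTC 3 and to 29130000, 26530000 and 25490000 for Gli2CA 1, Gli2CA 2 and Gli2CA 3.

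The libraries differed in complexity as well as depth. After thinning to 18780000 fragments each, NTC 1 and NTC 3 had a read in 11359 and 11569 genes, NTC 2 in 14077, and the Gli2CA libraries in 13990 to 15203. Levels of each library are therefore given for the gene lists that passed. Gli2CA libraries correlated with each other at Pearson r of 0.848 to 0.880 across the 12266 genes tested, and NTC libraries at 0.707 to 0.775. NTC 2 correlated with the Gli2CA libraries at 0.819 to 0.833, above its 0.730 with NTC 1 and 0.775 with NTC 3. The libraries therefore did not cluster by group alone. These are correlations across genes, which are not independent replicates. The labels do not say that the libraries of a group came from separate mice, so p-values measure the spread between these samples. Expression of the Hedgehog genes gave no check of the labels, since the altered cells were not the sorted population. Gli2 and its target Gli1 were listed at 0 in all 6 libraries. Ptch1, another target, was listed at 0, 0 and 0.011 FPKM in the NTC libraries and at 0.507 to 1.59 FPKM in the Gli2CA libraries, below the level at which genes were tested.

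**Figure D1:**
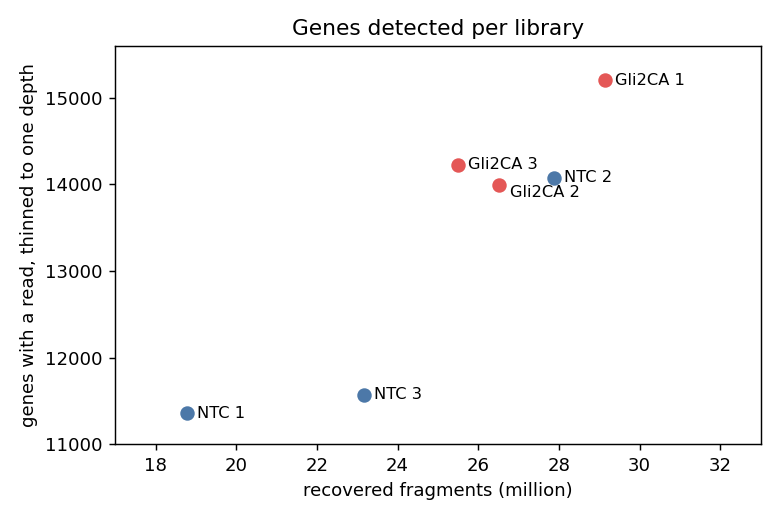
Genes with at least 1 read after thinning every library to 18780000 fragments (vertical axis, which does not start at 0) against the fragments recovered per library (horizontal axis), 1 point per library. NTC 1 and NTC 3 lie at 11359 and 11569 genes, and the other 4 libraries lie between 13990 and 15203.

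No single gene passed the test between the groups. With limma on log2(FPKM + 1), 0 of 12266 genes reached an adjusted p of 0.05, the smallest being 0.162, while 1304 had an unadjusted p under 0.05. Of those 1304, 959 had the higher mean in Gli2CA and 345 in NTC. The 1304 became 2450 without NTC 2, 817 without Gli2CA 1 and 393 with a replicate block by description number. The 3 libraries of a group lay wholly above those of the other in 2042 genes, 1332 higher and 710 lower in Gli2CA, or 16.6% of genes where chance gives 10%. After quantile normalization 21 genes passed, 18 higher and 3 lower. Among genes at an unadjusted p under 0.05 the higher share went from 73.5% to 61.5%, and it was 56.7% without both NTC 1 and NTC 3. The median difference of all genes went from 0.25 to -0.03 on the log2 scale, so gene groups are best read against that shift. Log2 differences below are Gli2CA minus NTC on the log2(FPKM + 1) scale, which understates the change of low genes.

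The protein-coding genes with the smallest p among those higher in Gli2CA were led by Tgfbi, a secreted matrix protein induced by TGF-beta. It lies at chromosome 13, 56609523 to 56639562 (GRCm38). Tgfbi stood at 1263 ± 96.1 FPKM in Gli2CA and 338 ± 80.7 in NTC (SD, n = 3 each), a log2 difference of 1.92 ± 0.21 (SE, limma adjusted p = 0.162). The others on this side were Prl2c3, Plaur, Ifit2, Slfn4, Ly6c2, Msr1, Ms4a6d, Fth1 and Moxd1. Plaur, the urokinase receptor, had 316 ± 35.02 against 79.5 ± 14.9 FPKM. Msr1, a scavenger receptor of macrophages, had 220 ± 64.8 against 33.2 ± 14.8 FPKM. Fth1, the ferritin heavy chain, had 9337 ± 2249 against 4335 ± 454 FPKM. Prl2c3 belongs to a family of near-identical genes, so its 55.2 ± 11.02 FPKM in Gli2CA is uncertain as to which copy it came from. The protein-coding genes with the smallest p among those lower in Gli2CA included Snx22, Ppt1, Asb2, Crebl2, Lsp1, Hgh1, Wars, Cst3 and Grap. The immunoglobulin gene Ighm is outside this ranking. Its log2 difference was -2.08 (limma adjusted p = 0.178, against 0.192 for Snx22). Cst3, a cysteine protease inhibitor abundant in dendritic cells, had 8293 ± 1288 FPKM in Gli2CA and 17650 ± 5835 in NTC. Lsp1, a leukocyte actin-binding protein, had 1493 ± 171 against 2736 ± 575 FPKM. None of the 10 protein-coding genes with the smallest p on each side passed (limma adjusted p of 0.162 to 0.209), and all 20 had non-overlapping groups. After quantile normalization 9 of them passed, namely Tgfbi, Plaur, Ifit2, Slfn4, Ly6c2, Msr1, Ms4a6d and Fth1 on the higher side and Lsp1 on the lower side.

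Gene lists for cell types and pathways, fixed before the data were examined, were tested as groups. Of 31 lists with at least 5 tested members, 12 differed by limma's camera test with a preset correlation between genes of 0.01, 7 higher and 5 lower in Gli2CA. With the correlation estimated from the data, 0 of the 31 passed, and the smallest adjusted p was 0.303. The 12 became 6 without NTC 2 and 7 without NTC 3. Ranges of list medians below are over the other settings and leave-outs with the preset correlation. Camera ranks a list against all other genes, whose median lay at 0.25.

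Type I interferon response genes rose as a group in the Gli2CA libraries. All 21 members had the higher mean there, with a median log2 difference of 1.30, range 1.02 to 1.75 (camera adjusted p = 4.69e-07; adjusted p = 0.303 with an estimated correlation). The list level, the mean log2(FPKM + 1) of its members, was 6.55, 6.31 and 6.83 in the Gli2CA libraries and 4.91, 4.94 and 5.28 in the NTC libraries, the value of NTC 2 being 4.94. Ifit2, an interferon-induced protein that restricts viral RNA translation, had 143 ± 34.7 FPKM in Gli2CA and 13.6 ± 6.08 in NTC. Irf7, the transcription factor that amplifies interferon production, had 1128 ± 297 against 453 ± 76.2 FPKM. Oasl1 had 127 ± 54.7 against 17.7 ± 11.5 FPKM, and Ifi44 had 27.3 ± 6.85 against 2.75 ± 1.52. Adjusted over the list alone, 11 of the 21 members passed, all higher, against 0 adjusted over all genes tested. The interferon gamma response list did not pass (adjusted p = 0.692), with 9 members higher and 9 lower. Within it Cxcl10, a T cell-attracting chemokine, had 259 ± 77.2 against 79.4 ± 8.37 FPKM, while its relative Cxcl9 had 171 ± 22.8 against 219 ± 20.6. Nos2 had 14.7 ± 11.1 FPKM in Gli2CA and 0.0052 ± 0.0090 in NTC.

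Glycolysis and hypoxia genes also rose as a group. All 20 members had the higher mean in Gli2CA, with a median log2 difference of 1.11, range 0.88 to 1.38 (camera adjusted p = 6.41e-06; adjusted p = 0.511 with an estimated correlation). The list level was 7.96, 7.84 and 7.21 in Gli2CA and 6.21, 6.60 and 5.70 in NTC, with 6.60 in NTC 2. Tpi1, a glycolytic enzyme, had 1423 ± 297 against 639 ± 16.3 FPKM, and Pkm, pyruvate kinase, had 2943 ± 651 against 1566 ± 58.0. The hypoxia-induced mitophagy receptor Bnip3 had 362 ± 146 against 66.7 ± 36.1 FPKM, and the hypoxia-induced carbonic anhydrase Car9 had 25.7 ± 7.11 against 1.86 ± 1.80. Adjusted over the list alone, 12 of the 20 members passed, all higher, against 0 over all genes.

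Markers of type 1 conventional dendritic cells (cDC1), the subset that cross-presents antigen to CD8 T cells, fell as a group. All 15 members had the lower mean in Gli2CA, 10 of them without overlap between the groups, with a median log2 difference of -0.89, range -1.17 to -0.78 (camera adjusted p = 1.48e-07; adjusted p = 0.303 with an estimated correlation). The list level was 5.60, 5.84 and 5.798 in Gli2CA and 6.96, 7.04 and 6.45 in NTC. Xcr1, the chemokine receptor that defines the subset, lies at chromosome 9, 123852315 to 123862029, and had 7.97 ± 3.11 FPKM against 39.3 ± 10.5. Clec9a, a receptor for dead cells, had 16.0 ± 2.59 against 40.5 ± 6.23 FPKM. The transcription factors Batf3 and Irf8 had 67.6 ± 25.6 against 250 ± 181 and 571 ± 80.3 against 1003 ± 343 FPKM. Snx22 had 9.27 ± 4.90 against 71.5 ± 17.6 FPKM. Of the 15, 8 passed when adjusted over the list alone, all lower, against 0 over all genes.

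The conventional dendritic cell core list fell more weakly, with 8 of 10 members lower and a median of -0.44, range -0.90 to -0.28, the latter without Gli2CA 1 (camera adjusted p = 0.0445; adjusted p = 0.511 with an estimated correlation). The level was 5.71, 6.25 and 5.99 in Gli2CA and 6.19, 6.64 and 6.39 in NTC, with overlap. None of its 10 members passed when adjusted over the list alone. Its member Itgax, which encodes CD11c itself, had 163 ± 54.9 FPKM in Gli2CA and 98.4 ± 31.2 in NTC. Flt3 had 43.6 ± 13.2 against 58.9 ± 20.2 FPKM and Zbtb46 had 17.2 ± 5.197 against 32.4 ± 26.0. This call was lost on leaving out NTC 1, NTC 2, NTC 3, Gli2CA 1 or Gli2CA 3, with adjusted p of 0.0702, 0.113, 0.0516, 0.134 and 0.0783, and also with a pseudocount of 0.1, a minimum mean of 5, rescaling to one sum, quantile normalization, and without both NTC 1 and NTC 3, a choice made after seeing the data. Type 2 conventional dendritic cell markers did not pass (median -0.37, range -0.77 to -0.12, the latter without NTC 3, camera adjusted p = 0.0719). They passed as lower in 3 of 21 other settings, among them without Gli2CA 2 (adjusted p = 0.0163). They also passed among genes at 20 FPKM or more in every library, a choice made after seeing the data (median -0.68, adjusted p = 0.00875). Of the type 2 markers, the lectin Mgl2 had 111 ± 92.6 against 307 ± 56.4 FPKM, and Cd209a had 962 ± 248 against 1193 ± 347. The mature regulatory dendritic cell list did not pass either (median -0.20, range -0.84 to -0.15, with -0.66 without NTC 1, camera adjusted p = 0.0755). It passed as lower in 2 of 21 other settings, among them without Gli2CA 2 (adjusted p = 0.0155), and its members went both ways. Ccr7, the receptor for migration to lymph nodes, had 72.3 ± 18.5 against 188 ± 78.4 FPKM, whereas Cd274, which encodes PD-L1, had 35.7 ± 8.87 against 9.51 ± 7.21. Plasmacytoid markers did not pass (median -0.25, range -0.87 to 0.36, camera adjusted p = 0.546). Their median changed sign with 1 library, to 0.34 without NTC 3, and was -0.61 without NTC 2.

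MHC class II presentation genes fell as a group, with 11 of 13 members lower and a median log2 difference of -0.36, range -0.45 to -0.16 (camera adjusted p = 0.0220; adjusted p = 0.511 with an estimated correlation). The level was 9.89, 10.09 and 10.16 in Gli2CA and 10.54, 10.18 and 10.40 in NTC, so NTC 2, at 10.18, lay beside the Gli2CA libraries. The class II chain gene H2-Ab1 had 29564 ± 3272 FPKM in Gli2CA and 36679 ± 5574 in NTC, and H2-DMb2 had 222 ± 50.8 against 448 ± 85.0. The 2 members with the higher mean were proteases, Lgmn at 405 ± 19.8 against 147 ± 31.3 FPKM and Ctss at 3479 ± 238 against 2292 ± 156. Adjusted over the list alone, 6 members passed as lower and these 2 as higher. The call was lost without NTC 1, NTC 3 or Gli2CA 1, with adjusted p of 0.136, 0.0575 and 0.0673, after quantile normalization (adjusted p = 0.313), with a replicate block by description number (adjusted p = 0.0971), and without both NTC 1 and NTC 3 (adjusted p = 0.675). MHC class I presentation did not pass (adjusted p = 0.248). Its member H2-K1 had 3178 ± 217 against 3420 ± 94.5 FPKM, and B2m had 6026 ± 505 against 4076 ± 357.

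Monocyte markers rose as a group, with 12 of 14 members higher and a median log2 difference of 1.03, range 0.50 to 1.34 and 0.67 without Gli2CA 2 (camera adjusted p = 0.0312; adjusted p = 0.407 with an estimated correlation). The list level was 6.68, 6.79 and 6.40 in Gli2CA and 5.36, 5.51 and 5.59 in NTC. Ly6c2, the surface marker of classical monocytes, had 592 ± 178 against 155 ± 33.3 FPKM. Cd14, a co-receptor for bacterial lipopolysaccharide, had 417 ± 155 against 67.8 ± 48.3, and Ms4a4c had 1323 ± 289 against 506 ± 120. Of its members, 4 passed when adjusted over the list alone, all higher. They included Nr4a1, which is also in the cAMP-CREB response list described below. The call was lost without NTC 2 (adjusted p = 0.220) and with a pseudocount of 0.1 (adjusted p = 0.0685). Macrophage markers did not pass (15 of 19 higher, median 0.59, range 0.31 to 0.84, camera adjusted p = 0.0804). They passed as higher in 5 of 21 other settings, among them without NTC 1 (adjusted p = 0.0158). They also passed among genes at 20 FPKM or more in every library, a choice made after seeing the data (median 0.39, adjusted p = 0.00616). In that list Spp1, which encodes osteopontin, had 1003 ± 646 against 53.9 ± 30.7 FPKM, Fcgr1 had 267 ± 32.8 against 94.7 ± 46.2, and Arg1, which depletes arginine, had 294 ± 210 against 42.7 ± 56.7 with overlapping groups. Neutrophil markers did not pass (median 1.64, range 0.26 to 2.74, with 0.46 without Gli2CA 3, camera adjusted p = 0.148). They passed as higher without Gli2CA 2 (adjusted p = 0.0155) and with a replicate block by description number (adjusted p = 0.00361). In the neutrophil list Il1r2 had 752 ± 179 against 91.9 ± 131 FPKM.

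Chemokines that recruit myeloid cells rose as a group, with 9 of 11 members higher and a median log2 difference of 1.99, range 1.40 to 4.28 (camera adjusted p = 0.00836; adjusted p = 0.511 with an estimated correlation). Per library the level was 5.49, 5.03 and 4.56 in Gli2CA and 4.07, 3.93 and 2.17 in NTC. Ccl12 had 173 ± 39.2 against 46.5 ± 30.2 FPKM, Cxcl2 had 138 ± 41.2 against 16.8 ± 15.3, and Ccl2 had 210 ± 132 against 40.2 ± 61.6. Of the 11, 6 passed when adjusted over the list alone, all higher. Leaving out NTC 2 ended the call (adjusted p = 0.0851). The NF-kB and inflammatory list, which shares Cxcl1, Cxcl2 and Cxcl3 with it, did not pass (13 of 17 higher, median 0.59, adjusted p = 0.0967). The inflammatory cytokine gene Il1b had 2455 ± 563 against 489 ± 369 FPKM in that list.

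The prostaglandin and eicosanoid list did not pass (11 of 15 higher, median 0.81, range 0.18 to 2.57, with 0.48 without Gli2CA 2, camera adjusted p = 0.174). It passed in 0 of 21 other settings. Ptgs2, which encodes the inducible cyclooxygenase COX-2, had 39.4 ± 6.92 FPKM in Gli2CA and 3.63 ± 6.18 in NTC, a log2 difference of 4.08 ± 1.05 (SE, limma adjusted p = 0.221) with no overlap. Its NTC values were 0.11, 10.8 and 0 FPKM, the 10.8 in NTC 2, and without both NTC 1 and NTC 3 the log2 difference was 1.76. The prostaglandin E2 receptor genes Ptger2 and Ptger4 had 4.39 ± 2.33 against 1.65 ± 2.86 and 6.32 ± 5.37 against 5.69 ± 4.19 FPKM. The cAMP-CREB response list, genes induced downstream of cyclic AMP, rose with 12 of 13 members higher and a median of 0.81, range 0.40 to 2.19, with 1.47 without NTC 1 and 1.62 without NTC 2 (camera adjusted p = 0.0147; adjusted p = 0.511 with an estimated correlation). Its level was 4.19, 4.52 and 4.70 in Gli2CA and 3.002, 4.02 and 2.43 in NTC, with NTC 2, at 4.02, near the Gli2CA libraries. The immediate early gene Nr4a1 had 179 ± 14.1 against 48.5 ± 20.1 FPKM, and Thbs1, which encodes thrombospondin, had 22.1 ± 4.57 against 1.52 ± 1.497. These 2 members passed when adjusted over the list alone. The call was lost without NTC 3 or Gli2CA 3 (adjusted p = 0.0646 and 0.0574) and with a replicate block by description number (adjusted p = 0.121). Genes induced by tissue dissociation rose too, and shared Fosb and Dusp1 with that list. Of these 16 genes, 15 were higher, with a median of 0.80, range 0.35 to 0.998 and 0.51 without NTC 3 (camera adjusted p = 0.0356; adjusted p = 0.511 with an estimated correlation). Their level was 7.16, 7.77 and 7.62 in Gli2CA and 6.78, 6.93 and 5.73 in NTC. Fos had 2216 ± 175 against 588 ± 413 FPKM, and Atf3 had 456 ± 88.9 against 159 ± 96.2. Leaving out NTC 2, NTC 3, Gli2CA 2 or Gli2CA 3 ended this call (adjusted p of 0.170, 0.0516, 0.203 and 0.0783), as did a pseudocount of 0.1 (adjusted p = 0.0941) and a replicate block by description number (adjusted p = 0.376).

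Wnt pathway targets did not pass (6 of 14 tested, median -0.44, range -0.71 to 0.10, camera adjusted p = 0.553). Neither did Wnt ligands and receptors (7 of 25 tested, median 0.95, range -0.25 to 2.03, camera adjusted p = 0.553). The other members of both lists lay below the tested level, so these results do not cover them. Cd44 had 136 ± 34.995 against 55.8 ± 16.5 FPKM, Myc 34.1 ± 13.9 against 44.8 ± 10.6, and Axin2 stayed below the tested level at 0.174 FPKM over all libraries. The tolerogenic and checkpoint list did not pass (11 of 16 higher, median 0.64, range 0.49 to 1.03, camera adjusted p = 0.0755). However, 5 members passed as higher when adjusted over the list alone. The list passed as higher in 4 of 21 other settings, among them quantile normalization (adjusted p = 0.0201). It also passed among genes at 20 FPKM or more in every library, a choice made after seeing the data (median 0.81, adjusted p = 0.00133). Hmox1, the heme-degrading enzyme, had 369 ± 236 against 58.1 ± 30.7 FPKM, and Il10 had 2.04 ± 1.71 against 5.31 ± 8.78. Ido1 was listed at 0 in all 6 libraries. The list of signals by which dendritic cells stimulate T cells did not pass (median 0.64, adjusted p = 0.314). In it Cd40 had 256 ± 56.5 against 128 ± 27.1 FPKM, Ccl5 had 650 ± 194 against 1289 ± 194, and Il12b had 24.7 ± 9.71 against 52.4 ± 28.3. Fatty acid oxidation (median 0.16, adjusted p = 0.582) and cholesterol synthesis (median 0.20, adjusted p = 0.673) did not pass. Cpt1a had 13.3 ± 2.27 against 19.3 ± 25.3 FPKM. Only 2 of 11 Hedgehog pathway genes reached the tested level, Smo and Sufu, and that list was not tested.

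Cell cycle genes fell as a group, with 16 of 20 members lower and a median of -0.47, range -0.75 to -0.41, with -0.75 without NTC 1 and -0.71 without Gli2CA 1 (camera adjusted p = 0.00136; adjusted p = 0.511 with an estimated correlation). The level was 4.94, 4.18 and 3.84 in Gli2CA and 4.21, 5.03 and 5.05 in NTC, with overlap. Mcm2, a replication helicase subunit, had 27.9 ± 16.4 against 130 ± 79.6 FPKM, and Mki67 had 3.17 ± 3.95 against 11.8 ± 3.43. The mitotic cyclin gene Ccnb1 went the other way at 19.997 ± 4.95 against 3.45 ± 5.92. No member passed over the list alone, and without both NTC 1 and NTC 3 the list did not pass (adjusted p = 0.0969).

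Markers of other cell types were present after the CD11c sort. T cell markers fell relative to all genes, with 13 of 18 lower and a median of -0.40, range -0.93 to -0.18, with -0.74 without NTC 1 and -0.18 without NTC 2 (camera adjusted p = 0.0321; adjusted p = 0.584 with an estimated correlation). The list level was 5.47, 5.74 and 5.91 in Gli2CA and 5.03, 6.66 and 5.63 in NTC, so NTC 2 held the most. Trac, the T cell receptor alpha constant gene, had 231 ± 39.1 against 553 ± 161 FPKM, and was the 1 member that passed over the list alone. Without NTC 2, NTC 3 or Gli2CA 1 the call was lost (adjusted p of 0.309, 0.0575 and 0.118), as after quantile normalization (adjusted p = 0.132), with a minimum mean of 5, with protein-coding genes alone, and with a replicate block by title or description number (adjusted p of 0.0522 and 0.118). Of 15 melanocytic tumour cell markers, 6 were tested, and these rose as a group. All 6 were higher, with a median of 1.64, range 1.13 to 5.47 (camera adjusted p = 0.00278, and 0.407 with an estimated correlation). The other members lay below the tested level, so this result does not cover them. Among those, the pigment genes Mlana, Tyr, Tyrp1 and Dct were listed at 0 in every library. Per library the list level, over all 15 members, was 1.59, 1.13 and 0.69 in Gli2CA and 0.33, 0.35 and 0.0014 in NTC. Sox10, a neural crest and melanocyte transcription factor at chromosome 15, 79154908 to 79165240, stood at 19.8, 12.1 and 18.4 FPKM in Gli2CA and was listed at 0 in each NTC library. With a floor of 3 reads per NTC library the log2 difference of Sox10 was at least 4.02; the list median of 1.64 is set by other members and cannot move with it. Mcam had 31.9 ± 35.2 against 0.021 ± 0.019 FPKM, and these 2 genes passed over the list alone. The call was lost without NTC 2 (adjusted p = 0.0851). The NK and cytotoxic (adjusted p = 0.936), B and plasma cell (0.553), fibroblast and matrix (0.692) and endothelial (0.627) lists did not pass. Their medians and means were above 0 while the test of the first 3 pointed down against all genes, as it did for the interferon gamma and cholesterol lists and, with a median of -0.07 and a mean of 0.02, for MHC class I. Gzma had 62.8 ± 19.97 against 9.83 ± 10.1 FPKM, and Ighm had 143 ± 42.7 against 601 ± 130. Fibroblast and matrix genes were highest in NTC 2, at a list level of 4.91 against 1.07 to 2.95 in the other libraries. Mast cell, keratinocyte and erythroid lists had too few tested members for a test, with mean levels of 1.08, 0.65 and 2.46 in Gli2CA and 0.77, 0.19 and 2.37 in NTC. Within the keratinocyte list Krt14 stood at 46.2, 4.04 and 21.5 FPKM in Gli2CA and was listed at 0 in NTC.

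**Figure D2:**
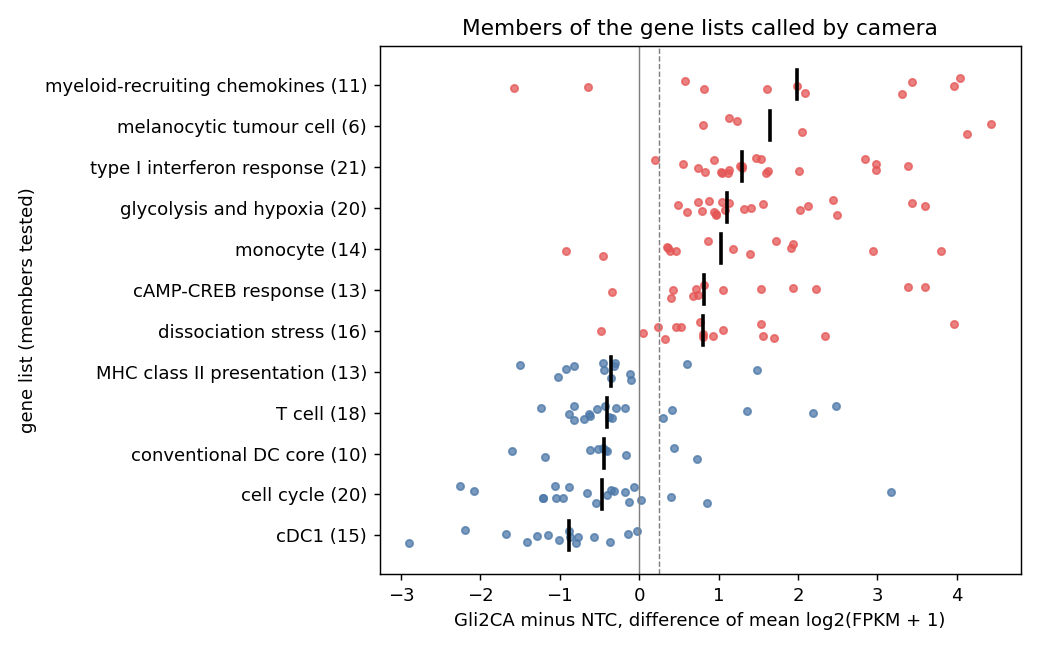
Difference between the Gli2CA and NTC means of log2(FPKM + 1) (horizontal axis) for each tested member of the 12 lists called by camera (vertical axis, number of members in parentheses). Each point is a gene, red in lists called higher and blue in lists called lower, the black bar is the list median, the solid line is 0 and the dashed line is the median of all genes, 0.25. All 21 interferon and all 20 glycolysis and hypoxia members lie above 0, and all 15 cDC1 members lie below 0.

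**Figure D3:**
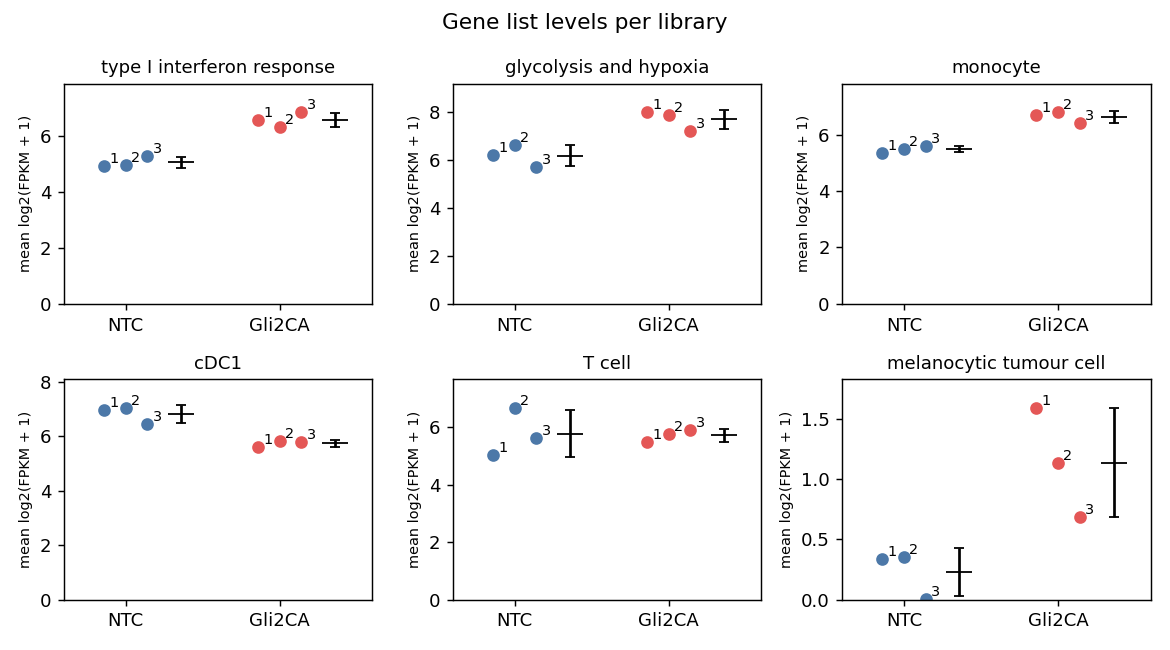
Mean log2(FPKM + 1) over the members of 6 gene lists (vertical axis, from 0) in each library, NTC in blue and Gli2CA in red, numbered by replicate, with the group mean and SD (n = 3) in black. The interferon, glycolysis, monocyte and cDC1 levels of the groups do not overlap, while the T cell level of NTC 2, 6.66, lies above the Gli2CA levels of 5.47 to 5.91.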

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

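The voom, minimum mean of 20 and joint leave-out settings were chosen after seeing the data. No gene was called in any alternative except quantile normalization, which called 21 genes, 18 higher and 3 lower in Gli2CA; the cause was not tested. Voom on the recovered reads called 0, with 1624 at an unadjusted p under 0.05. The numbers of lists higher and lower were 7 and 5 in the main test. They were 7 and 3 with a minimum mean of 5, 9 and 2 after quantile normalization, 9 and 3 without both NTC 1 and NTC 3, 0 and 0 with camera and an estimated correlation, and 3 and 0 with fry, where the monocyte, interferon and melanocytic lists passed. Fewer genes or samples enter some of these; otherwise the cause was not tested. Leaving out 1 replicate at a time gave 3 to 8 lists higher and 2 to 7 lower, with 3 and 3 without NTC 2. The interferon, glycolysis and cDC1 lists passed, in the main direction, in all 21 refits with camera at the preset correlation, the cell cycle and chemokine lists in 20, monocyte in 19, cAMP-CREB in 18, dissociation stress and MHC class II in 15, T cell in 13, the dendritic cell core in 11, and the melanocytic list in 18 of 19. Replicate numbers gave no sign of pairing: deviations of libraries with the same title number correlated at -0.042, -0.002 and -0.007. All pairs across the groups lay between -0.064 and 0.074, so these values cannot tell whether the numbers pair animals. A replicate block by title number called 0 genes and 7 and 4 lists, and by description number 0 genes and 6 and 3 lists. No library correlated best with the library of its own number in the other group. Over the refits, 59 list values lost and 19 gained a call out of 701, and 13 gene values out of 3298 gained one. None reversed a call; the sign changed without a call in 26 list and 57 gene values. With a pseudocount of 0.1 the level difference of 6 of 17 marker lists moved by over 1 SD and 4 changed sign. Count models, planned if the table held counts, were not run. Depth limits the lowest values: 1 read at the median gene length is worth 0.0338 FPKM in NTC 1 and 0.0218 in Gli2CA 1.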

Other observations

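All tests and expectations in this part were written after the data were seen, as were the thresholds of 1, 10 and 20 FPKM. The comparison over other splits of the libraries was set by the design, but what it should show was written afterwards.

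Gene families named by symbol were each tested against all other genes. Of 15 families defined, 14 had enough tested members and were tested together, and the Ifi200 family of interferon-inducible genes had 10 of 11 members higher in Gli2CA, with a median log2 difference of 1.22 (camera adjusted p = 0.000509; adjusted p = 0.444 with an estimated correlation). All 9 tested members of the Ms4a family of membrane proteins were higher (median 1.10, adjusted p = 0.00131; adjusted p = 0.451 with an estimated correlation), as were 6 of 7 Schlafen genes (median 1.19, adjusted p = 0.0181; adjusted p = 0.444 with an estimated correlation) and 11 of 12 S100 genes (median 0.71, adjusted p = 0.00954; adjusted p = 0.462 with an estimated correlation). These medians stayed above 0 with rescaling to one sum, median-of-ratios scaling and quantile normalization, as did that of the mitochondrially encoded genes below, while those of the ribosomal and oxidative phosphorylation genes stayed below 0. Members of such families can share reads, and some are also in the lists of the report: Ifi205 in cDC1, Ms4a4c in monocyte, Ms4a7 in macrophage, and S100a8 and S100a9 in neutrophil. Ms4a6d and Slfn4 were also among the higher genes with the smallest p named above. The Ms4a and Schlafen results are therefore not independent of that ranking. The Gbp family of interferon gamma-induced GTPases had 4 members higher and 4 lower (adjusted p = 0.726). Ifitm genes (4 of 5 higher, median 0.81, adjusted p = 0.0399) and annexins (8 of 10 higher, median 0.57, adjusted p = 0.0438) passed in the main setting but not with median-of-ratios scaling (adjusted p of 0.0504 and 0.0591) or an estimated correlation (adjusted p = 0.490 for both); after quantile normalization annexins passed (adjusted p = 0.0254) and Ifitm genes did not (adjusted p = 0.0726). Cathepsins (adjusted p = 0.189), proteasome subunits (0.0945), vacuolar ATPase subunits (0.944) and heat shock proteins (0.963) did not pass.

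Genes of the cytosolic ribosome and nuclear genes of respiration went the other way, but mitochondrially encoded genes did not. The test set them against all genes, whose median lay at 0.25. Genes at 20 FPKM or more in every library had a median of -0.09, and the respiration median of -0.15 lay near it. The groups did not overlap in 2 higher and 2 lower ribosomal genes and in 2 higher and 9 lower respiration genes. The share over all genes tested was 16.6%. Of 82 cytosolic ribosomal protein genes, 63 were lower in Gli2CA, with a median of -0.26 (camera adjusted p = 0.000329; adjusted p = 0.566 with an estimated correlation). Of 77 nuclear genes for oxidative phosphorylation subunits, 56 were lower, with a median of -0.15 (adjusted p = 0.000509; adjusted p = 0.490 with an estimated correlation), which did not pass after quantile normalization (adjusted p = 0.0967). All 20 mitochondrially encoded genes had the higher mean in Gli2CA (median 0.78, adjusted p = 0.000509; adjusted p = 0.490 with an estimated correlation). Their share of all FPKM was 0.716 to 0.777% in the Gli2CA libraries, 0.714% in NTC 2, 0.355% in NTC 1 and 0.297% in NTC 3, so NTC 2 lay beside the Gli2CA libraries.

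The first pattern is the shift of the interferon, glycolysis, monocyte and cDC1 lists. Loss of transcripts in NTC 1 and NTC 3 is argued against as the whole cause of the rises among them. All of these lists still passed among the 2747 genes at 20 FPKM or more in every library, whose median was -0.09. The medians of the 10, 11, 8 and 8 members left were 1.07, 0.94, 0.43 and -0.78 (camera adjusted p of 8.56e-07, 1.76e-08, 0.00122 and 0.00129). These p-values used the preset correlation of 0.01, and an estimated correlation was not run on these genes. The monocyte median was below the 1.03 of its whole list. Lost transcripts have lower NTC values, so the passing of the cDC1 list, which was higher in NTC, says little about loss. Of the other lists called in the main test, the dendritic cell core and MHC class II lists did not pass there (adjusted p of 0.317 and 0.0833). The cell cycle, T cell and dissociation stress lists did (adjusted p of 0.0479, 0.00639 and 0.00129). The cAMP-CREB, chemokine and melanocytic lists had too few members left for a test. A smaller share of dendritic cells in the sort would raise markers of all other types alike and cannot be told apart from a rise of monocytes or a change within cells: the monocyte level minus the T cell level was 1.20 ± 0.50 (SE, n = 3 each) higher in Gli2CA, with no overlap (exact permutation p = 0.1, the smallest possible), but 0.77 ± 0.29 without NTC 2, and it lay within 2 SE of 0 without NTC 3 (1.32 ± 0.78) or Gli2CA 2 (1.14 ± 0.57). The 10 splits of the 6 libraries are too few for a share under 0.05: the real split called 12 lists and 1 of 10 gave as many, with 6 the highest of the others. It had 1304 genes at an unadjusted p under 0.05 (2450 without NTC 2 and 817 without Gli2CA 1), against 1006 for the highest other, which set NTC 1, NTC 3 and Gli2CA 3 apart (1 of 10 as many), and called 0 genes, as did the others (10 of 10). The effect of Gli2 in the tumour cells is the biological explanation the design names, and stays open and untested beyond these values.

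The second pattern, noticed after the values were seen, is a set of 15 genes at 10 FPKM or more in every Gli2CA library and under 1 in every NTC library: Prl2c3, Moxd1, Aqp5, Tnnt2, Tspan15, Tinagl1, Anxa8, Aspa, Gm14039, Layn, Id1, Flrt3, Sox10, Tubb3 and 3830403N18Rik. The reverse held for 0 genes, and the other 18 choices of 3 libraries gave at most 7. The reverse needed 10 FPKM or more in NTC 1 and NTC 3, where fewer genes were detected. Its count is therefore not directly comparable with the 15. Pigmented melanoma cells passing the CD11c gate are argued against as the source, since 4 of 5 pigment genes (Mlana, Tyr, Tyrp1 and Dct) had 0 reads in all Gli2CA libraries and the other, Pmel, reached 2.88 FPKM in Gli2CA 1. RNA of unpigmented tumour cells may contribute. Without a profile of the implanted line it cannot be told apart from expression in sorted cells or RNA of other cell types. The 5 tested melanocytic markers that are neither pigment genes nor among the 15 had a median log2 difference of 1.24. Gli2 and Gli1 were listed at 0 in every library. Of the keratinocyte markers tested, Krt14 had a log2 difference of 4.13 and Krt10 of 0.10. A keratinocyte source was not tested. Loss in NTC 1 and NTC 3 as the whole cause predicts no larger a share in NTC 2 than in a Gli2CA library. Of 201 genes high in Gli2CA and under 1 FPKM in both, 7.46% were also under 1 in NTC 2. With each Gli2CA library in its place in turn, the share was 2.43%, or 12 of 494 entries summed over those libraries. A gene can enter under several libraries, so the 494 are not separate genes. The comparison goes against loss but rests on NTC 2 alone and excludes nothing.

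The third pattern is the lower number of genes detected in NTC 1 and NTC 3. Sequencing depth is argued against as the cause, since at equal depth the lowest of the other libraries still had 2421 more genes with a read than the higher of these. Fewer distinct RNA molecules in these libraries is a possible explanation: of genes at 20 FPKM or more in the other 5 libraries, 142 were under 1 FPKM in NTC 1 and 55 in NTC 3, against at most 2 in any other library. Both affected libraries are NTC and NTC 2 had 0 such genes, which leaves a link to the group open. No record of input amounts was used here, so the reason stays open.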
